A study of Arabidopsis thaliana with 8 samples.

How the data were processed

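The samples were 8 libraries of polyadenylated RNA from Arabidopsis thaliana seedlings, 2 for each of 4 groups: the wild type in darkness and in blue light, the cry1 cry2 mutant in blue light, and the tir1 afb1 afb2 afb3 mutant in darkness. Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.2 to TAIR10. The deposited values were RPKM per gene model, per the file headers, for 27416 models, and neither the annotation release nor the way reads were assigned to genes was given. Reads that fit paralogs equally well can move between such genes, which concerns above all the LHCB1, RBCS and SAUR19 to SAUR24 families. Symbols and the order of genes came from the RefSeq annotation of TAIR10.1, which held 26719 of the models, and the other 697 kept their locus names. No coordinates are given, since the builds may differ. Of 1043 models with low values, 1042 had values that were whole multiples of a single step to within 0.02, which allowed the total reads behind each library and the reads of each model to be recovered. The recovered totals were 19.3 M and 20.2 M for the dark wild type, 23.0 M and 20.8 M for the wild type in blue light, 23.1 M and 21.7 M for cry1 cry2, and 22.2 M and 21.3 M for the auxin receptor mutant. Recovered reads were whole to within 0.01 reads for all 24717 models above 0. On simulated tables the recovery found 8 of 8 totals and the exact reads of 1996 of 2000 genes.

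Tests used limma 3.58.1 in R 4.3.3, with eBayes and a mean-variance trend, on log2 of RPKM + 1. Genes with at least 1 RPKM in at least 2 libraries were tested, 20044 in all, in a single fit of the 8 libraries and 4 groups with 4 residual degrees of freedom and 6.96 prior degrees of freedom. A Benjamini-Hochberg adjusted p under 0.05 counted as changed, without a fold minimum unless stated. The contrasts were blue light in the wild type, cry1 cry2 against the wild type in blue light, the auxin receptor mutant against the wild type in darkness, and cry1 cry2 in blue light against the dark wild type. Genes passing at an unadjusted p under 0.05 numbered 15214, 14144, 16062 and 9934 in turn. The SD between replicates was 0.109 to 0.118 on the log2 scale, taken from the spread of their differences over all tested genes. The variance between the 2 libraries of a group was 2.63 to 4.45 times what counting alone gives, as chi-square per degree of freedom. That ratio was 1.22 to 1.27 for genes under 200 reads and 6.77 to 14.5 for genes of at least 2000 reads. In a principal component analysis the first axes held 52.6%, 38.5% and 6.92% of the variance, and the libraries of a group lay together. The test was run on a simulated comparison of blue light in the wild type with 19036 genes and 50 changed genes per fold size. It found 8% of the 1.25-fold, 74% of the 1.5-fold, 96% of the 2-fold and 100% of the 4-fold changes, with 13 wrong calls. Few genes changed in the simulation, whereas 74.4% of tested genes passed for blue light in the data, where the adjusted threshold is less strict. The percents found therefore do not carry over to the data. Groups of 2 libraries are too small to test single libraries as outliers or to count other groupings of the samples.

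The 21 gene lists were Aux/IAA, GH3, SAUR, auxin synthesis, transport and perception, light-harvesting and photosystem, Calvin cycle, chlorophyll synthesis, flavonoid and anthocyanin, light signalling, circadian clock, expansins and XTH, brassinosteroid, gibberellin, ethylene and apical hook, sugar starvation and darkness, root hair, root tissue, seed storage and reserve, abiotic stress and handling, defence and jasmonate, and reference genes, with 385 genes in all. Counts of members follow the test over all genes, and were repeated with the adjustment over the list alone. The shift of a list against other genes was tested with camera in limma at its preset correlation of 0.01 between genes and again with the correlation estimated from the data. The latter form rests on the 4 residual degrees of freedom of the fit, which by its construction makes its calls rarer. The rotation test fry asks instead whether the members moved in a common direction, without reference to other genes. Its mixed form asks whether they moved in either direction. Adjustment ran over the 21 lists of a contrast. Named genes were the 6 mutated genes, the 6 largest rises and 6 largest falls among passing genes with at least 5 RPKM on average and no overlap between the replicate values of the groups, up to 3 risen and 3 fallen members of each list, HY5, CHS, IAA19, YUC8 and PIF4, and the 5 leading genes of each direction of an overlap. The lists, tests, thresholds, alternatives and the rule for named genes were fixed before the data were examined. Overlaps of gene calls were tested with Fisher's exact test, and the overlap that shared libraries give without any changed gene was simulated in 20 draws.

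Levels of the mutated genes are given as a percent of the wild type with exact 95% intervals from recovered reads. Alternatives were no filter on low values, a filter at 5 RPKM, fits of only the 2 groups compared, the replicate number as a block, each library left out in turn, upper-quartile scaling, quantile normalization, no mean-variance trend, pseudocounts of 0.1 and 0.5, and a fold minimum of 2. Analysis of the recovered reads with limma-voom, and a split of the blue-light wild-type libraries so that the first 2 contrasts share none, were added after the data had been seen.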

Results

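The series measured polyadenylated RNA in Arabidopsis thaliana seedlings of the Col-0 accession. Seedlings stood for 3 days in the cold and 12 h in white light, then for 4 days in darkness or in blue light of 15 µmol per m2 per s, on medium with 1% sucrose. There were 4 groups of 2 libraries: wild type in darkness, wild type in blue light, the cry1 cry2 double mutant in blue light, and the tir1 afb1 afb2 afb3 quadruple mutant in darkness. CRY1 and CRY2 are the blue light receptors called cryptochromes, and TIR1 and AFB1 to AFB3 are auxin receptors. The stated question was which genes depend on cryptochrome-mediated blue light signalling and which on the TIR1/AFB receptors. The files gave RPKM for 27416 gene models, with 19.3 M to 23.1 M reads behind each library. Values are means ± SD of the 2 libraries of a group, and log2 fold changes compare RPKM + 1 and carry their standard error (SE). A gene is said to have risen or fallen only at a limma adjusted p under 0.05. The labels do not say whether the 2 libraries of a group came from separate cultures, so each p measures the spread between these samples, which may be technical.

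The mutated genes were read first. In the cry1 cry2 libraries CRY2 (AT1G04400) had 5 reads against 6244 in the wild type in blue light, which is 0.0782% of the wild-type level (exact 95% interval 0.0254% to 0.183%). CRY1 (AT4G08920) stayed at 72.1% of the wild-type level (69.1% to 75.2%), 33.3 ± 0.665 against 46.1 ± 1.33 RPKM. In the quadruple mutant AFB2 (AT3G26810) stood at 1.56% (1.24% to 1.94%) and AFB1 (AT4G03190) at 3.2% (2.58% to 3.87%) of the dark wild type. AFB3 (AT1G12820) stood at 50.2% (47.3% to 53.3%) and TIR1 (AT3G62980) at 77.1% (74.5% to 79.8%), so for CRY1, TIR1 and AFB3 the amount of transcript alone did not identify the mutant. These intervals cover counting error only.

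**Figure D1:**
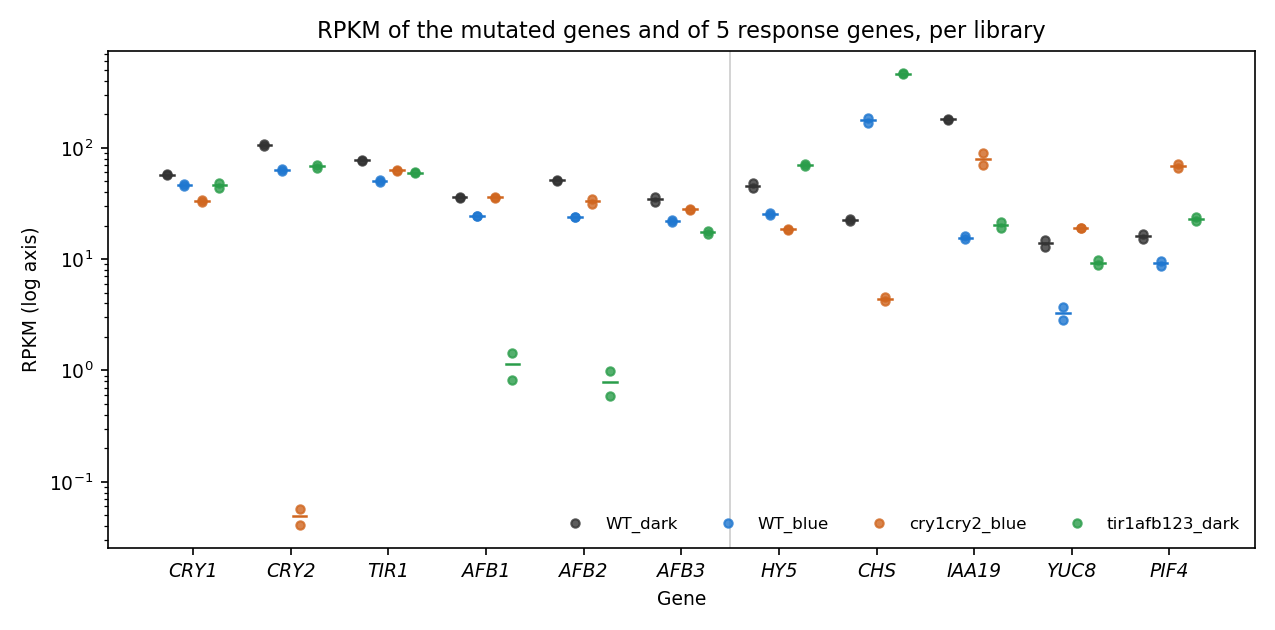
RPKM (log axis) of the 6 mutated genes and of 5 genes that respond to light or auxin, with 1 point per library and a bar for the mean of each group. CRY2 lay near 0.0491 RPKM in cry1 cry2, and IAA19 fell from 180.2 RPKM in the dark wild type to 15.6 RPKM in blue light.

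The first comparison asked what blue light did to the wild type. Genes of photosynthesis and carbon fixation were higher in blue light, and genes of auxin response, brassinosteroids, the apical hook and sugar starvation were lower. The Rubisco activase RCA (AT2G39730) went from 226 ± 0.0229 RPKM in darkness to 3310.1 ± 138 RPKM in blue light (log2 fold change 3.87, SE 0.07). PORA (AT5G54190), the protochlorophyllide reductase of dark-grown seedlings, went from 609 ± 31.3 to 1.88 ± 2.51 RPKM (-8.07, SE 0.45, and -9.11 without WT_blue replicate 1 or -7.03 without replicate 2). The auxin-induced repressor IAA19 (AT3G15540) went from 180.2 ± 4.01 to 15.6 ± 0.659 RPKM (-3.45, SE 0.10). The 6 largest rises were those of FBA5, an aldolase (8.42, SE 0.09, from 0.368 ± 0.0400 to 468 ± 7.23 RPKM), CT-BMY, a chloroplast beta-amylase (7.08, SE 0.09), AT1G23130 (6.80, SE 0.07), AOC2 of jasmonate synthesis (6.37, SE 0.08), ECS1 (6.27, SE 0.08) and THI1 of thiamine synthesis (6.14, SE 0.06). After PORA, the largest falls were those of the cell wall enzyme XTH15 (-6.42, SE 0.10, from 2659 ± 94.0 to 30.3 ± 5.25 RPKM), AT4G25580 (-6.27, SE 0.07), AT5G44440 (-5.90, SE 0.08), AT2G47780 (-5.46, SE 0.18) and AT1G19530 (-5.44, SE 0.08).

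The 4 auxin lists fell together in blue light. Of 26 measured Aux/IAA genes, the early auxin-induced repressors, 20 fell, 1 rose (IAA28, 0.56, SE 0.10) and 5 did not pass, and IAA20 (-5.18, SE 0.10) and IAA6 (-2.70, SE 0.11) were among the falls. The list's median log2 fold change was -0.70, and its shift against other genes (camera adjusted p = 0.000253) was not called with adjusted p = 0.329 with an estimated correlation. Of 32 SAUR genes, 27 fell, 3 rose and 2 did not pass, at a median of -1.104. SAUR25 (-3.58, SE 0.17) and SAUR9 (-2.98, SE 0.13) fell, while SAUR14 (2.36, SE 0.08) and SAUR6 (2.29, SE 0.07) rose. The SAUR list had a camera adjusted p = 0.00012 and an adjusted p = 0.401 with an estimated correlation. Of 7 GH3 genes, which conjugate auxin, 5 fell, none rose and 2 did not pass, GH3.5 the most (-2.24, SE 0.06). The GH3 median was -0.52, with camera adjusted p = 0.0468 and adjusted p = 0.401 with an estimated correlation, and the call was also lost when some single libraries were left out. Of 21 genes of auxin synthesis, transport and perception, 15 fell, 3 rose and 3 did not pass, with YUC8 of auxin synthesis at -1.81, SE 0.11 among the falls and YUC9 at 0.84, SE 0.11 among the rises. That list had a camera adjusted p = 0.0103 and an adjusted p = 0.427 with an estimated correlation.

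Of 42 light-harvesting and photosystem genes, 37 rose and 5 fell, at a median of 1.89. LHCA1 (3.42, SE 0.08) and PSBO2 (3.31, SE 0.08) rose, while the antenna genes LHCB4.2 (-2.14, SE 0.06) and LHCB2.3 (-2.18, SE 0.10) fell. The list had a camera adjusted p = 9.7e-12 and an adjusted p = 0.401 with an estimated correlation. All 13 Calvin cycle genes rose, at a median of 2.75, with RBCS1B at 3.85, SE 0.07 and FBA1 at 3.85, SE 0.07 (camera adjusted p = 2.6e-09, adjusted p = 0.329 with an estimated correlation). Of 18 chlorophyll synthesis genes, 13 rose, 3 fell and 2 did not pass, with PORC (2.73, SE 0.07) and DVR (2.55, SE 0.09) up and PORB (-2.44, SE 0.06) down beside PORA. Their camera adjusted p was 0.00312, with an adjusted p = 0.431 with an estimated correlation. Of 18 flavonoid and anthocyanin genes, 11 rose, 3 fell and 4 did not pass, FLS1 (3.75, SE 0.09) and CHS (2.91, SE 0.07) up and the regulator PAP1 (-1.41, SE 0.13) down (camera adjusted p = 0.00293, adjusted p = 0.255 with an estimated correlation).

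Growth and darkness lists moved the other way. All 16 brassinosteroid genes fell, at a median of -1.05, with the growth regulators PRE6 at -3.38, SE 0.08 and PRE1 at -1.96, SE 0.09 (camera adjusted p = 2.3e-05, adjusted p = 0.169 with an estimated correlation). Of 15 gibberellin genes, 12 fell and 2 rose, with GASA4 at -3.14, SE 0.10 down and GA3OX2 at 1.67, SE 0.16 up (camera adjusted p = 0.00393, adjusted p = 0.329 with an estimated correlation). All 9 ethylene and apical hook genes fell, at a median of -2.26, among them the hook regulator HLS1 (-2.66, SE 0.10) and the ethylene synthesis gene ACS5 (-3.12, SE 0.13). Their camera adjusted p was 0.00012, with an adjusted p = 0.329 with an estimated correlation. All 7 sugar starvation and darkness genes fell, at a median of -3.55, DIN6 the most (-5.02, SE 0.07). Here camera gave an adjusted p = 8.5e-05, and an adjusted p = 0.304 with an estimated correlation. The 24 expansins and XTH genes split into 8 risen, such as EXPA1 (2.31, SE 0.06), and 15 fallen, such as XTH30 (-2.65, SE 0.06). The limma camera adjusted p of that list was 0.105. Light signalling genes also split, 14 risen and 22 fallen of 38, with the cryptochrome inhibitor BIC1 at 3.94, SE 0.18, the photoreceptor gene PHYA at -3.01, SE 0.06 and the regulators HY5 and PIF4 at -0.82, SE 0.06 and -0.73, SE 0.08. Their camera adjusted p was 0.271. Of 17 clock genes, 4 rose, ELF4 the most (3.84, SE 0.05), and 10 fell, LNK2 the most (-1.92, SE 0.07), at the same camera adjusted p = 0.271.

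Among markers of other tissues and of handling, 11 of 15 root hair markers rose, none fell, and the median was 0.51, with RHS19 at 1.09, SE 0.10 (camera adjusted p = 0.0161, adjusted p = 0.401 with an estimated correlation). Of 15 root tissue markers, 12 fell and 2 rose, with the Casparian strip gene CASP5 at -3.41, SE 0.07 down and the iron transporter IRT1 at 1.01, SE 0.12 up (camera adjusted p = 0.00369, adjusted p = 0.401 with an estimated correlation). Of 15 seed storage and reserve genes, 3 rose and 4 fell, with the oleosin gene OLE2 at 1.98, SE 0.16, ICL at -3.20, SE 0.51 and a median of -0.02 (camera adjusted p = 0.915). The 2 blue-light libraries of ICL differed (45.3 and 7.94 RPKM), and its value was -4.38 without WT_blue replicate 1 and -2.01 without replicate 2. Of 13 stress and handling genes, 4 rose and 8 fell, with KIN1 at 1.77, SE 0.18 and the alcohol dehydrogenase ADH1 at -2.24, SE 0.11. Of 3 measured defence and jasmonate genes, LOX2 (5.89, SE 0.13) and VSP1 rose and VSP2 fell. Of 6 reference genes, 1 rose and 3 fell, between -0.64 for UBQ10 and 0.44 for EF1A.

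In all, 6818 genes rose and 8099 fell of 20044 tested, and 2237 and 1888 of them did so by at least 2-fold. Which direction held more calls depended on scaling, with 7547 risen and 7255 fallen after upper-quartile scaling. Adjusted over the list alone, 20 of the 21 lists had the same counts and the chlorophyll list had 14 risen members. Of 14 lists that camera called at its preset correlation, 0 were called with an estimated correlation, where the lowest adjusted p was 0.169 and 3 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether the members of a list moved in a common direction, called 19 lists, and its mixed form called 21. The reference genes were among the 19 (fry adjusted p = 0.000375). With 74.4% of tested genes changed, a fry call does not set a list apart from other genes.

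**Figure D2:**
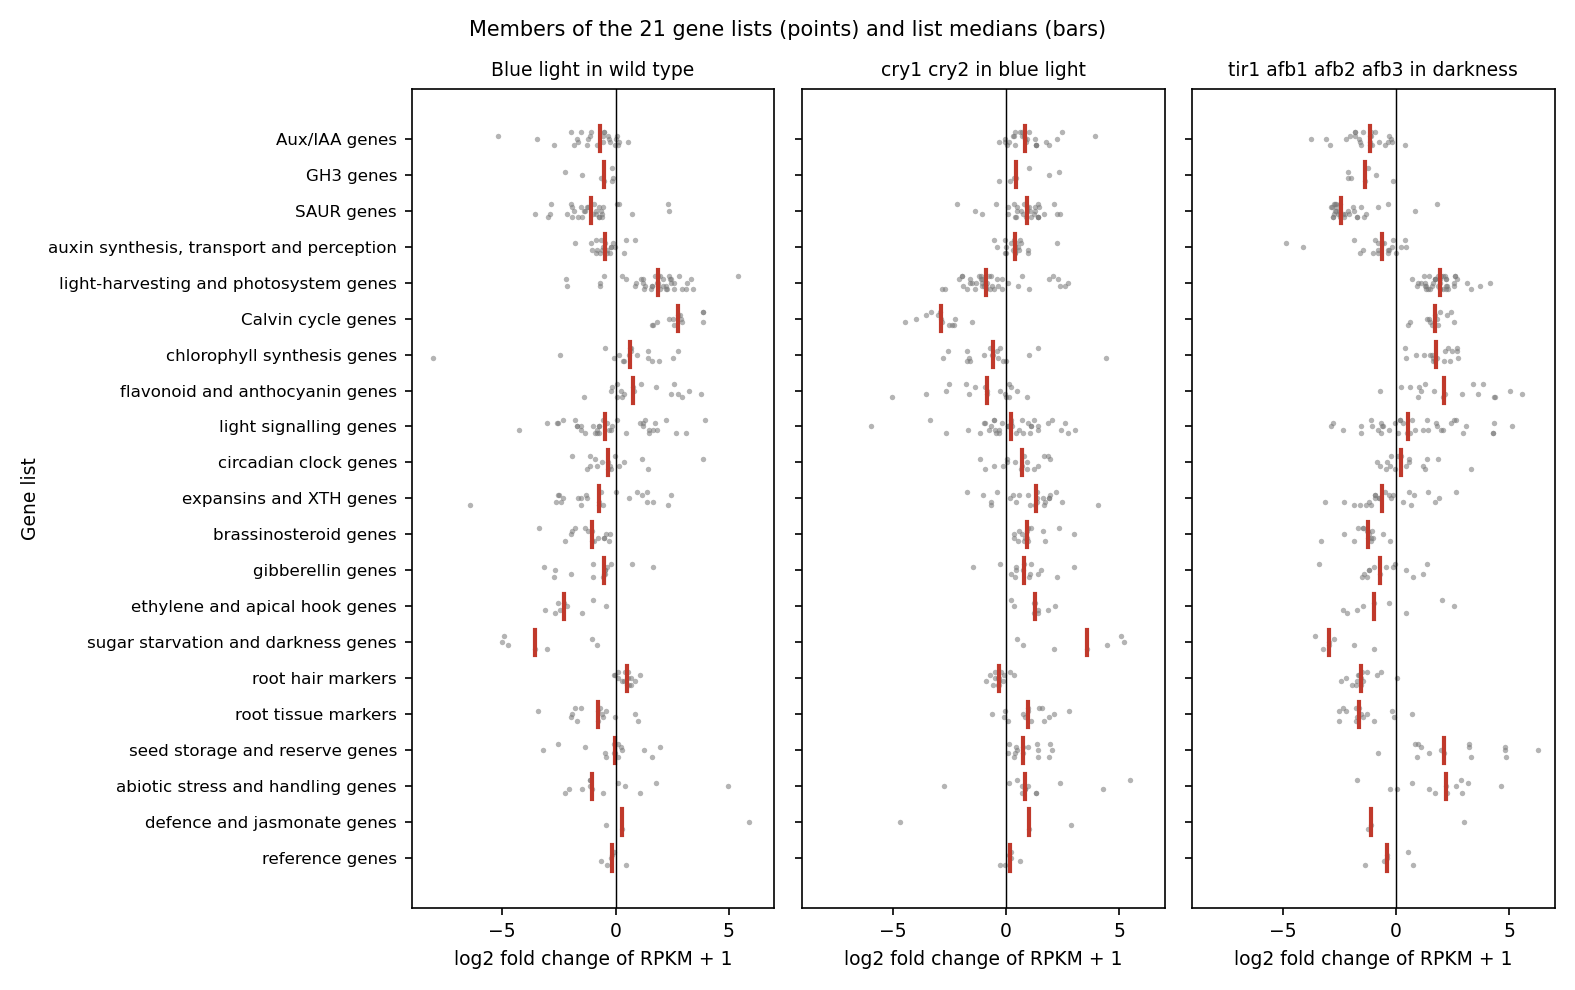
log2 fold change of RPKM + 1 for each measured member of the 21 gene lists (points) and the list median (bars) in 3 comparisons. The Calvin cycle medians were 2.75 for blue light, -2.84 for cry1 cry2 in blue light and 1.72 for the auxin receptor mutant in darkness.

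The second comparison set cry1 cry2 against the wild type, both in blue light. Most groups that blue light had raised in the wild type were lower in the mutant, and most that it had lowered were higher. RBCS1B (AT5G38430), a Rubisco small subunit, had 233 ± 19.3 RPKM in the mutant against 5127 ± 211 in the wild type (-4.45, SE 0.07). CHS (AT5G13930), which starts flavonoid synthesis, had 4.37 ± 0.232 against 176 ± 14.6 RPKM (-5.04, SE 0.07), and IAA19 had 79.8 ± 14.1 against 15.6 ± 0.659 RPKM (2.28, SE 0.10). The dehydrin RAB18 (AT5G66400), an abscisic acid response gene, had 569 ± 97.3 against 11.8 ± 0.358 RPKM (5.47, SE 0.09).

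Besides CRY2, the largest falls in the mutant were those of c-NAD-MDH1, FBA5 (-6.43, SE 0.09), AT1G04420, MSRB6 (-5.49, SE 0.11) and CHS. Genes next to CRY2 were looked up after their values were seen. The genes c-NAD-MDH1 (AT1G04410), a cytosolic malate dehydrogenase, and AT1G04420 directly follow CRY2 in the gene order of the TAIR10.1 assembly. The malate dehydrogenase had 0.266 ± 0.201 RPKM in the mutant against 479.5 ± 17.2 RPKM in the wild type in blue light and 597 ± 2.50 RPKM in darkness. AT1G04420 had 0 reads in the 2 mutant libraries against 4395 in the wild type. The next measured gene on each side, AT1G04390 and AT1G04430, stood at 145% and 115% of the wild type. The largest rises were those of AT4G25580 (6.59, SE 0.07), RAB18, the asparagine synthetase DIN6 (5.21, SE 0.07), SIS (5.10, SE 0.06), AT5G44440 (5.10, SE 0.08) and the aminotransferase BCAT2 (5.08, SE 0.08).

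**Figure D3:**
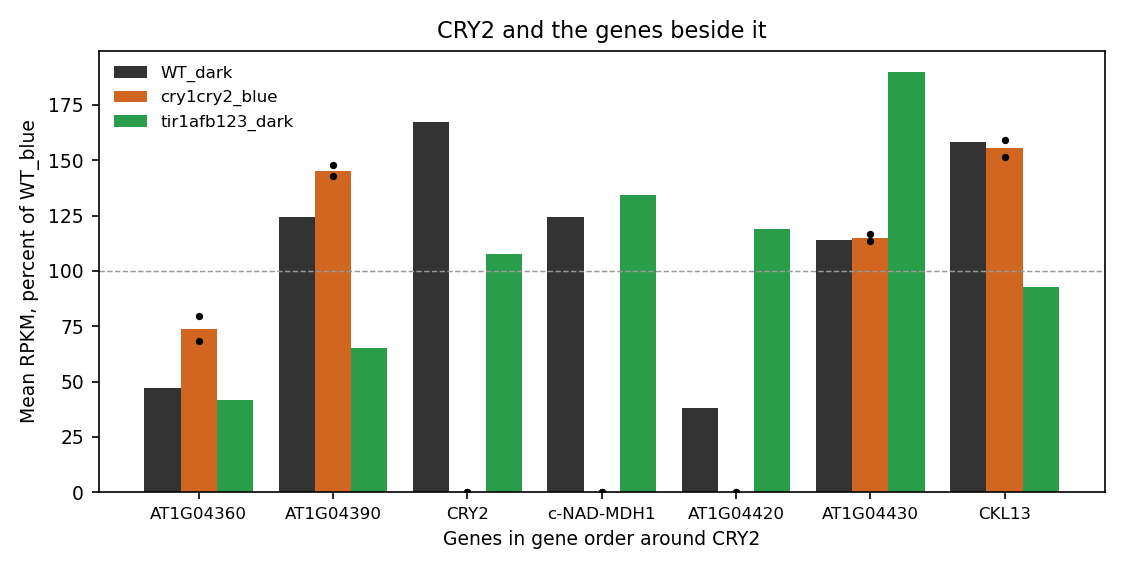
Mean RPKM as a percent of the wild type in blue light, for CRY2 and the genes beside it in gene order. Bars are group means, black points are the 2 cry1 cry2 libraries, and genes under 1 RPKM in WT_blue are left out. The bars of cry1 cry2 lie near 0 for CRY2 (0.0777%), c-NAD-MDH1 (0.0556%) and AT1G04420.

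Of the 26 Aux/IAA genes, 21 rose in the mutant, 1 fell and 4 did not pass, with IAA20 at 3.94, SE 0.10 and IAA5 at 2.48, SE 0.11 (median 0.83, camera adjusted p = 6.3e-05, adjusted p = 0.254 with an estimated correlation). Of the 32 SAUR genes, 26 rose, 4 fell and 2 did not pass (median 0.93, camera adjusted p = 0.00131, adjusted p = 0.409 with an estimated correlation). SAUR28 (2.12, SE 0.10) rose and SAUR6 (-2.16, SE 0.07) fell. Of the 7 GH3 genes, 5 rose and 1 fell, with GH3.5 at 2.35, SE 0.06 and GH3.3 at 1.89, SE 0.09 (median 0.46, camera adjusted p = 0.0484, adjusted p = 0.399 with an estimated correlation). This call too was lost when some single libraries were left out, with only 2 groups fitted and with smaller pseudocounts. Of the 21 genes of auxin synthesis, transport and perception, 15 rose and 2 fell, with YUC8 at 2.24, SE 0.11 and the efflux carrier PIN3 at 0.99, SE 0.06. That list had a camera adjusted p = 0.0181 and an adjusted p = 0.409 with an estimated correlation.

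All 13 Calvin cycle genes fell, at a median of -2.84 (camera adjusted p = 1.5e-12, adjusted p = 0.254 with an estimated correlation). Of 42 light-harvesting and photosystem genes, 30 fell, 9 rose and 3 did not pass, at a median of -0.86 and a mean of -0.51. PSBQ1 (-2.80, SE 0.06) fell, while LHCB2.2 (2.75, SE 0.08), LHCB4.2 (2.62, SE 0.06) and LHCB2.1 (2.41, SE 0.08) rose. The list had a camera adjusted p = 3.7e-06 and an adjusted p = 0.409 with an estimated correlation. Of 18 chlorophyll synthesis genes, 13 fell and 3 rose, with DVR at -2.76, SE 0.09 and PORC at -2.53, SE 0.07 down and PORA at 4.44, SE 0.45 up (5.48 and 3.4 without WT_blue replicate 1 or 2, camera adjusted p = 0.000234, adjusted p = 0.399 with an estimated correlation). Of 18 flavonoid genes, 10 fell and 3 rose, with FLS1 at -3.53, SE 0.09 (camera adjusted p = 0.00129, adjusted p = 0.154 with an estimated correlation).

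All 16 brassinosteroid genes rose, PRE1 the most (3.02, SE 0.09), at a median of 0.94 (camera adjusted p = 1.6e-05, adjusted p = 0.154 with an estimated correlation). Of 15 gibberellin genes, 13 rose and 1 fell, with GASA4 at 3.01, SE 0.10 (camera adjusted p = 0.00177, adjusted p = 0.254 with an estimated correlation). All 9 ethylene and apical hook genes rose, with ERS2 at 2.17, SE 0.09 and HLS1 at 1.44, SE 0.10 (camera adjusted p = 0.000971, adjusted p = 0.258 with an estimated correlation). All 7 darkness genes rose, at a median of 3.59 (camera adjusted p = 7.4e-05, adjusted p = 0.231 with an estimated correlation). Of 24 expansins and XTH genes, 18 rose and 5 fell, with XTH15 at 4.05, SE 0.10 up and XTH9 at -1.70, SE 0.06 down (camera adjusted p = 0.000971, adjusted p = 0.295 with an estimated correlation). Among light signalling genes, 18 rose and 15 fell of 38, with BBX28 (3.05, SE 0.07) and the growth regulator PIF4 (2.76, SE 0.08) up and BIC1 (-3.35, SE 0.18) and HY5 (-0.44, SE 0.06) down (camera adjusted p = 0.665). The mutated CRY2 (-5.93) was among the 15. Of 17 clock genes, 11 rose and 3 fell, with LNK1 at 1.93, SE 0.10 up and ELF4 at -1.15, SE 0.05 down (camera adjusted p = 0.0345, adjusted p = 0.409 with an estimated correlation).

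Of 15 root hair markers, 10 fell, PRP1 the most (-0.89, SE 0.17), and 1 rose, at a median of -0.31 (camera adjusted p = 0.0133, adjusted p = 0.346 with an estimated correlation). Of 15 root tissue markers, 11 rose and 1 fell, with CASP5 at 2.77, SE 0.07 (camera adjusted p = 0.00134, adjusted p = 0.346 with an estimated correlation). Of 15 seed storage and reserve genes, 10 rose and none fell, with PCK1 of gluconeogenesis at 1.96, SE 0.06 (camera adjusted p = 0.0133, adjusted p = 0.409 with an estimated correlation). Of 13 stress and handling genes, 11 rose and 1 fell, with RD29B at 4.27, SE 0.09 beside RAB18 and with COR15A at -2.72, SE 0.40 (camera adjusted p = 0.00129, adjusted p = 0.154 with an estimated correlation). The 2 mutant libraries of COR15A differed (1.72 and 7.87 RPKM), and its value was -1.87 without cry1cry2_blue replicate 1 and -3.57 without replicate 2. Of 3 defence and jasmonate genes, VSP2 (2.87, SE 0.12) and VSP1 rose and LOX2 (-4.65, SE 0.13) fell, so that the median was 1.01 and the mean -0.26. Of 6 reference genes, 3 rose and 1 fell, between -0.26 for EF1A and 0.62 for UBQ10. In all, 8337 genes rose and 5265 fell of 20044 tested, 1394 and 1480 of them by at least 2-fold. The lean towards higher calls depended on scaling: the median of all genes was 0.12, against 0.04 with upper-quartile scaling (7019 risen, 6149 fallen) and 0.06 with quantile normalization (7385 risen, 5997 fallen). Adjusted over the list alone, 20 lists had the same counts and the photosystem list had 32 fallen members. Of 18 lists called by limma camera, 0 were called with an estimated correlation (4 had an unadjusted p under 0.05), while fry called 21. The latter held the reference genes too (fry adjusted p = 0.000466).

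The third comparison set the auxin receptor mutant against the wild type, both in darkness. The mutant had lower levels of nearly all auxin response genes and of root markers, and higher levels of photosynthesis, flavonoid and seed reserve genes. IAA19 had 20.2 ± 1.71 RPKM in the mutant against 180.2 ± 4.01 in the wild type (-3.10, SE 0.10). The antenna gene LHCA1 (AT3G54890) had 618 ± 1.84 against 62.5 ± 2.71 RPKM (3.29, SE 0.08), and CHS had 463 against 22.5 ± 0.959 RPKM (4.31, SE 0.07). The largest rises were those of ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle (14291 ± 595 against 186 ± 6.86 RPKM, 6.26, SE 0.51), AT4G12870 (5.59, SE 0.15), the flavonol synthase FLS1 (5.53, SE 0.09), the transcription factor RRTF1 (5.32, SE 0.10), the early light-induced gene ELIP1 (5.12, SE 0.05) and AT1G80130 (5.10, SE 0.15). The largest falls were those of AFB2 (-4.87, SE 0.10), AT4G25580 (-4.81, SE 0.07), AT2G16005 (-4.42, SE 0.11), MRD1 (-4.33, SE 0.08), AT4G11320 (-4.13, SE 0.07) and AFB1 (-4.13, SE 0.11).

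Of the 26 Aux/IAA genes, 25 fell and 1 rose (IAA11), with IAA29 at -3.76, SE 0.09 and IAA6 at -2.92, SE 0.11 (median -1.16, camera adjusted p = 3.6e-05, adjusted p = 0.232 with an estimated correlation). Of the 32 SAUR genes, 30 fell, with SAUR50 at -2.86, SE 0.08 and SAUR22 at -2.82, SE 0.13, while SAUR6 and SAUR14 rose (median -2.41, camera adjusted p = 3.4e-06, adjusted p = 0.284 with an estimated correlation). Of the 7 GH3 genes, 6 fell and none rose, GH3.2 the most (-2.14, SE 0.14, median -1.38, camera adjusted p = 0.0144, adjusted p = 0.284 with an estimated correlation). Of the 21 genes of auxin synthesis, transport and perception, 4 of which are the mutated receptors, 16 fell and 3 rose, with the influx carrier AUX1 at -1.86, SE 0.05 and YUC8 at -0.54, SE 0.11. That list had a camera adjusted p = 0.0188 and an adjusted p = 0.458 with an estimated correlation.

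All 42 light-harvesting and photosystem genes rose, at a median of 1.93, with LHCB2.2 at 4.14, SE 0.08 (camera adjusted p = 9.2e-23, adjusted p = 0.232 with an estimated correlation). All 13 Calvin cycle genes rose, with RBCS1B at 2.54, SE 0.07 (median 1.72, camera adjusted p = 5.5e-09, adjusted p = 0.235 with an estimated correlation). All 18 chlorophyll synthesis genes rose, with DVR at 2.71, SE 0.09 and GUN4 at 2.70, SE 0.07 (median 1.74, camera adjusted p = 5e-11, adjusted p = 0.232 with an estimated correlation). Of 18 flavonoid genes, 17 rose and 1 fell, with F3H at 5.04, SE 0.09 and PAP1 at 4.36, SE 0.13 (median 2.097, camera adjusted p = 6.7e-09, adjusted p = 0.0583 with an estimated correlation). Of 38 light signalling genes, 22 rose and 13 fell, with ELIP2 at 4.34, SE 0.11, the growth regulator ATHB2 at -2.87, SE 0.06, HY5 at 0.60, SE 0.06 and PIF4 at 0.49, SE 0.08 (camera adjusted p = 0.00134, adjusted p = 0.384 with an estimated correlation). Of 17 clock genes, 9 rose and 6 fell, with PRR9 at 3.29, SE 0.11 (camera adjusted p = 0.0315, adjusted p = 0.445 with an estimated correlation).

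All 16 brassinosteroid genes fell, IBH1 the most (-3.32, SE 0.08, median -1.25, camera adjusted p = 6e-05, adjusted p = 0.08 with an estimated correlation). All 7 darkness genes fell, with BCAT2 at -3.58, SE 0.08 (median -2.96, camera adjusted p = 0.000735, adjusted p = 0.232 with an estimated correlation). Gibberellin genes split into 4 risen and 9 fallen of 15, with GASA6 at -3.40, SE 0.12. Ethylene and hook genes split into 3 risen, such as ACS6 (2.57, SE 0.09), and 6 fallen, such as HLS1 (-2.18, SE 0.10). Expansins and XTH genes split into 8 risen, such as XTH9 (2.63, SE 0.06), and 15 fallen, such as XTH30 (-3.14, SE 0.06), and camera called none of these 3 lists, with adjusted p between 0.359 and 0.737.

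Of 15 root hair markers, 14 fell and none rose, with PRP1 at -2.45, SE 0.17 and PRP3 at -2.20, SE 0.11 (median -1.56, camera adjusted p = 0.000843, adjusted p = 0.232 with an estimated correlation). Of 15 root tissue markers, 12 fell and 1 rose, with MRN1 at -2.54, SE 0.10 and CASP5 at -2.53, SE 0.07 (median -1.64, camera adjusted p = 0.00134, adjusted p = 0.284 with an estimated correlation). Of 15 seed storage and reserve genes, 14 rose and 1 fell, with the malate synthase MLS at 4.80, SE 0.17 and the storage protein gene CRU1 at 4.84, SE 0.22 (median 2.12, camera adjusted p = 1.2e-06, adjusted p = 0.232 with an estimated correlation). Of 13 stress and handling genes, 10 rose and 2 fell, with WRKY40 at 4.62, SE 0.10 and RD29A at 2.93, SE 0.10 (median 2.22, camera adjusted p = 5.7e-05, adjusted p = 0.08 with an estimated correlation). Of 3 defence and jasmonate genes, LOX2 rose (3.00, SE 0.13) and VSP1 and VSP2 fell, so that the median was -1.11 and the mean 0.21. Of 6 reference genes, 2 rose and 4 fell, between -1.39 for ACT2 and 0.75 for EF1A.

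In all, 5521 genes rose and 10295 fell of 20044 tested, 2109 and 3186 of them by at least 2-fold. The median of all genes was -0.24, and it was -0.10 after upper-quartile scaling and -0.05 after quantile normalization, with 6703 risen and 8684 fallen, then 7025 risen and 8212 fallen. Every list median and named gene above kept its sign in this comparison under these 2 scalings. Adjusted over the list alone, 20 lists had the same counts and the light signalling list had 23 risen members. Of 16 lists called by limma camera, 0 were called with an estimated correlation (3 had an unadjusted p under 0.05), while fry called 21. Here too the reference genes were among those that fry called (fry adjusted p = 0.000118).

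Next came the distance of cry1 cry2 in blue light from the dark wild type, where genotype and light differ together. Most photosystem genes were above the dark level in the mutant, 38 of 42 risen and 1 fallen at a median of 1.00, with LHCA1 at 3.24, SE 0.08 (camera adjusted p = 6.7e-20, adjusted p = 0.498 with an estimated correlation). Calvin cycle genes lay on both sides, 4 risen and 6 fallen of 13, with RCA at 0.94, SE 0.07 and RBCS2B at -1.41, SE 0.07. Of 32 SAUR genes, 15 were lower and 3 higher (camera adjusted p = 0.000237, adjusted p = 0.688 with an estimated correlation), and adjusted over the list alone 21 were lower. Of 9 ethylene and hook genes, 7 were lower (camera adjusted p = 5.1e-05, adjusted p = 0.498 with an estimated correlation). Of 17 clock genes, 12 were higher and 3 lower (camera adjusted p = 0.00402, adjusted p = 0.597 with an estimated correlation). All 3 defence and jasmonate genes were higher, at the same camera adjusted p = 0.00402 and with an adjusted p = 0.498 with an estimated correlation. The count was 5028 genes higher and 3313 lower, 586 and 315 of them by at least 2-fold, so 901 in all. After quantile normalization 3931 were higher and 4098 lower. The count of 901 depended on the pseudocount and on the method. Adjusted over the list alone, 10 lists had the same counts and 11 did not. Of 5 lists called by limma camera, 0 were called with an estimated correlation (1 had an unadjusted p under 0.05). For a common direction fry called 11, the SAUR list not among them (adjusted p = 0.0621). Its mixed form called 20, the SAUR list among them (fry mixed adjusted p = 0.000502). Medians and means had opposite signs for the Aux/IAA list (0.01 and -0.09), the auxin synthesis list (0.05 and -0.03), the Calvin list (0.05 and -0.16), the light signalling list (0.16 and -0.01) and the reference genes (0.0124 and -0.00461). The light signalling list holds the mutated CRY2, whose -6.67 was its lowest value and pulled its mean down.

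Candidates for blue-light genes that depend on the cryptochromes were counted as those that moved in opposite directions in the first 2 comparisons. There were 4903 that rose in blue light and were lower in cry1 cry2, and 6923 that fell and were higher, 11826 in all and 1360 plus 1020 at 2-fold in each comparison. FBA5, CT-BMY, AOC2, MSRB6 and AT3G28270 led the former, and AT4G25580, AT5G44440, ORP4C, DIN6 and BCAT2 the latter. Among 230 genes that were higher in each comparison were KIN1 (2.40, SE 0.18 in the mutant) and the storage protein gene CRU1, and among 63 that were lower in each were HY5 and CRY2 itself. The comparisons share the blue-light wild-type libraries. In 20 simulated draws without any change, shared libraries alone gave 0.2 opposite calls on average and a correlation of -0.50 across genes, against 11826 and -0.88 observed. The covariance was -0.699 observed against -0.00509 simulated. Without any changed gene almost no call was possible in these draws, so they cannot say what overlap shared libraries give among changed genes. With the libraries split, so that each served only 1 comparison (an alternative chosen after the overlap was seen), 10308 and 10125 genes were called in opposite directions in the 2 ways round, with correlations of -0.87. Without a dark cry1 cry2 group, dependence on the cryptochromes in light cannot be told from an effect of genotype without light. Nor can it be told from an effect of the lost neighbours of CRY2. One of them, AT1G04420, had 26.3 RPKM in the dark wild type, 69.3 in blue light and 0 in the mutant.

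For the 2237 genes risen at least 2-fold in blue light, the mutant kept a median of 24.5% of the log2 response, and 94.9% were lower in the mutant than in the wild type in blue light. For the 1888 fallen genes it kept 27.4%, and 94.8% were higher in the mutant. The share kept was 52.3% over 33 risen photosystem genes, 1.82% over the 13 Calvin cycle genes and 2.22% over 6 fallen darkness genes. It was 69.9% over 3 risen clock genes and 66.2% over 6 risen expansins and XTH genes. Its median exceeded the response of the wild type over 3 risen seed reserve genes (138%) and 3 risen stress genes (224%). In each of the latter 2 sets 2 genes were called above the wild type in blue light, and 1 stress gene was called below it. The fallen members of these 4 lists kept less: 19.1% over 4 clock genes, 17.6% over 11 expansins and XTH genes, 36.9% over 3 seed reserve genes and 19.7% over 7 stress genes. Since the share divides by the blue-light change, shared libraries enter it too, and differences between lists in this share were not tested.

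The last comparison asked whether genes changed in cry1 cry2 were also changed in the auxin receptor mutant, which shares no library with it. Of genes at least 2-fold higher in cry1 cry2, 761 were at least 2-fold lower in the auxin receptor mutant, against 222 for independent lists (odds ratio 8.04, 95% interval 7.17 to 9.03). Of genes at least 2-fold lower in cry1 cry2, 873 were at least 2-fold higher in the auxin receptor mutant, against 156 (odds ratio 20.2, 17.9 to 22.7). Only 106 were higher in each against 147 (odds ratio 0.684, 0.553 to 0.839), and 27 lower in each against 235 (odds ratio 0.0906, 0.0594 to 0.133). AT4G25580, BCAT2, AT2G39855, AT4G17470 and the aquaporin gene BETA-TIP led the pair higher in cry1 cry2 and lower in the auxin receptor mutant. CHS, FLS1, AT1G72610, TIR and AT3G56290 led the reverse pair. LHCB2.1, LHCB2.2, AT1G80130, AT1G15010 and KIN1 led those higher in each, and AT1G67870, PELPK2, AT1G06830, AT1G47395 and AT3G49960 those lower in each. Without a fold minimum 6373 genes were higher in cry1 cry2 and lower in the auxin receptor mutant, against 4282 (odds ratio 6.44, 6.04 to 6.87). Genes are not independent, so the intervals are too narrow. The light and auxin comparisons, which share the dark wild type, had 1066 genes at least 2-fold higher in each against 235 for independent lists, and 1076 at least 2-fold lower in each against 300.1. In opposite directions there were 71 higher in blue light and lower in the auxin receptor mutant, and 108 of the reverse. Over all calls 9920 genes went in the same direction, with a correlation of 0.52 and a covariance of 0.515. Simulated draws without any change gave 0.05 such calls, a correlation of 0.50 and a covariance of 0.00513. Without any changed gene almost no call was possible in these draws. They therefore cannot say what overlap the shared dark wild type gives among changed genes, and its libraries were not split for this pair.

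**Figure D4:**
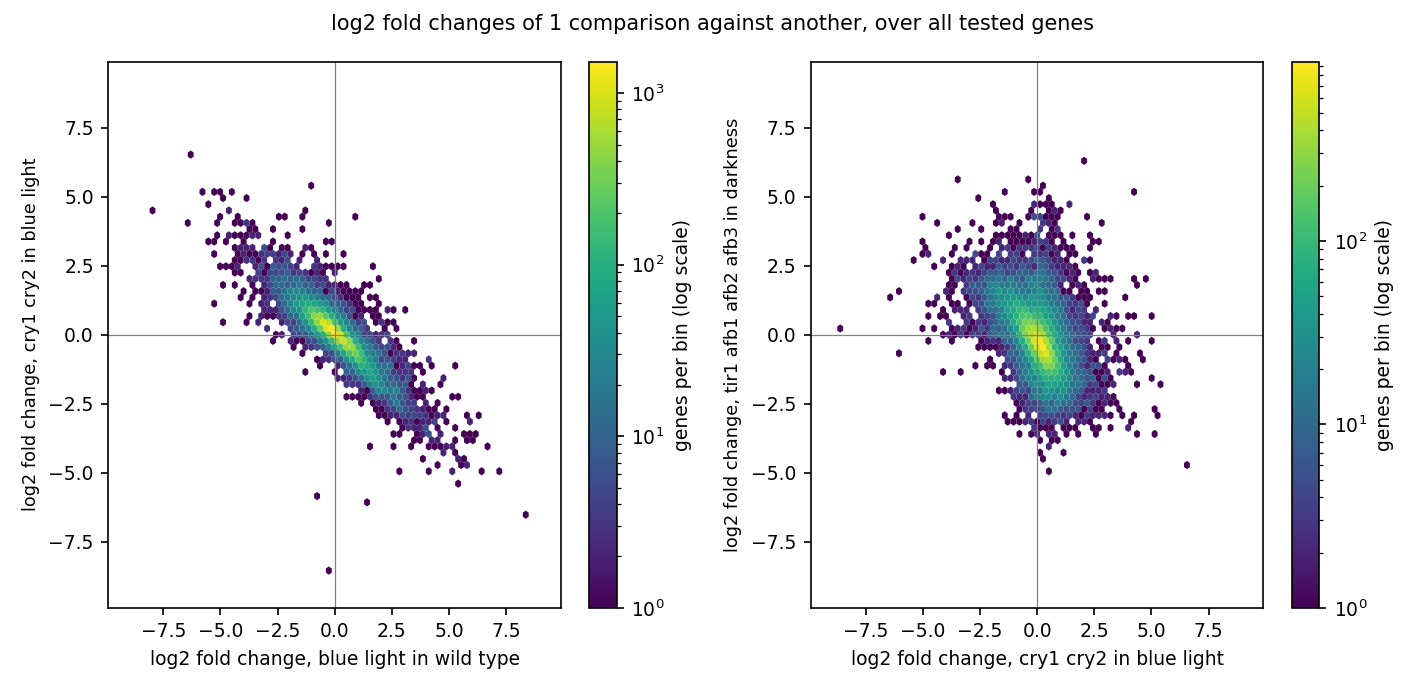
log2 fold changes of 20044 tested genes, as counts of genes per hexagonal bin on a log color scale, for cry1 cry2 in blue light against blue light in the wild type (left) and for the auxin receptor mutant in darkness against cry1 cry2 in blue light (right). The left cloud runs from upper left to lower right (correlation -0.88 across genes, and -0.87 with the shared libraries split).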

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

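Limma-voom and the split of the blue-light wild-type libraries between comparisons were chosen after the data were seen, and the other alternatives before. Of the counts of genes, 218 values lay within 1.5 times the reported ones and 8 moved further. Of the values of named genes, 7108 kept direction and call, 43 lost the call and 0 turned direction. Of the values of the Aux/IAA, GH3, SAUR and photosystem lists, 180 kept direction and call and 24 lost the call, and of those of the other lists 824 kept them, 37 lost the call and 6 turned. Models that left out a library assumed that the lone sample of its group varies like the other groups. Groups of 2 libraries limit each p to the spread between these samples, and depth limits genes near 1 RPKM, where a pseudocount of 1 shrinks folds.

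Genes at least 2-fold apart between cry1 cry2 in blue light and the dark wild type numbered 1391 with a pseudocount of 0.1 and 1446 with limma-voom on recovered reads, against 901. A smaller pseudocount by its construction widens the folds of low genes. Limma-voom works on reads without the added 1 RPKM, so by its construction it lacks that shrinkage too. Other causes of its count were not tested. A fold minimum of 2 left by its construction fewer genes: 4125 for blue light, 2874 for cry1 cry2, 5295 for the auxin receptor mutant, 901 for cry1 cry2 against the dark wild type, 2380 of the opposite pair and 761 of the pair higher in cry1 cry2 and lower in the auxin receptor mutant.

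With an estimated correlation camera called none of the Aux/IAA (-0.702, 0.830, -1.16), GH3 (-0.517, 0.462, -1.38), SAUR (-1.104, 0.928, -2.41) and photosystem lists (1.885, -0.859, 1.93), medians in the order blue light, cry1 cry2, auxin receptor mutant, which were those of the preset correlation. The estimates were 0.144, 0.234, 0.330 and 0.697 in the order of these lists, against the preset 0.01. A higher correlation by its construction weakens camera. The brassinosteroid list lost its blue-light call too (camera adjusted p = 0.169) at an estimate of 0.00255, so a higher correlation was not the cause for that list. In this form camera also refers its statistic to the 4 residual degrees of freedom of the fit, which by its construction weakens any call. A call lost in this form therefore does not show that a list did not shift. Causes of the following losses were not tested. The GH3 call for blue light was lost with a filter at 5 RPKM (-0.654) and a pseudocount of 0.1 (-0.668). It was also lost without WT_dark replicate 2, WT_blue replicate 1 or either auxin receptor mutant library. Over all 8 libraries left out in turn its medians were -0.597 to -0.437. The GH3 call for cry1 cry2 was lost with only 2 groups fitted (0.462) and pseudocounts of 0.1 (0.522) and 0.5 (0.494). It was also lost without cry1cry2_blue replicate 1 (0.394) or either auxin receptor mutant library (0.462 each). Over all 8 libraries left out in turn its medians were 0.394 to 0.559. The direction of the camera test, called in none of these cases, turned for the defence list without a filter (0.00442 for cry1 cry2, -0.189 for the auxin receptor mutant). It also turned for the seed list in blue light with only 2 groups fitted (-0.0234), a pseudocount of 0.1 (-0.171) and without either cry1 cry2 library (-0.0234 each). Over all 8 libraries left out in turn the medians of that list were -0.0658 to 0.0190.

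With the replicate number as a block, the counts were 14873 for blue light, 13491 for cry1 cry2 and 15756 for the auxin receptor mutant. The deviations of replicates 1 and 2 correlated between groups at -0.12 to 0.14, so libraries of the same number shared no strong deviation. Whether the numbers mark a shared culture or harvest stays open.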

Other observations

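The 4 gene groups in this and the next paragraph were chosen after their values were seen, so their p describe the pattern and are no independent test. Their camera p were adjusted over these 4 groups of a contrast alone, apart from the lists fixed before the data were examined. A smaller set by its construction makes the adjustment milder, so calls here cannot be set beside those of the earlier lists. Genes of aliphatic glucosinolate synthesis were higher in the wild type in blue light than in darkness or in cry1 cry2. All 10 measured genes rose in blue light, at a median log2 fold change of 3.77 (4.11 with MYB29, at 0 reads in darkness, at its bound), with limma camera adjusted p = 8.3e-07 and adjusted p = 0.0442 with an estimated correlation. The regulator MYB28 went from 1.06 ± 0.0352 to 35.3 ± 0.294 RPKM and the enzyme gene CYP83A1 from 0.233 ± 0.00772 to 53.6 ± 3.39 RPKM (n = 2). All 10 fell in cry1 cry2, at a median of -2.30 (camera adjusted p = 1.7e-08, adjusted p = 0.0309 with an estimated correlation), where CYP79F1 had 0.0116 ± 0.0165 RPKM against 16.3 ± 1.65 in the wild type. Of 7 genes of indole glucosinolate synthesis, 3 rose and 2 fell in blue light, and 4 rose and 2 fell in cry1 cry2.

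Genes that respond fast to wounding and touch were higher in the auxin receptor mutant. All 18 rose, at a median of 3.83 (3.91 with JAZ8, at 0 reads in the wild type, at its bound), with camera adjusted p = 2.2e-13 and adjusted p = 0.00496 with an estimated correlation. The transcription factors RRTF1 and ERF13 had 70.8 ± 0.811 and 51.3 ± 1.77 RPKM against 0.803 ± 0.0251 and 0.573 ± 0.211, and the jasmonate repressor JAZ1 had 160.4 ± 4.55 against 22.5 ± 1.14. Of 18 abscisic acid response genes, 17 rose in cry1 cry2 and none fell, at a median of 2.195 (camera adjusted p = 7.5e-09, adjusted p = 0.2 with an estimated correlation). LEA7 had a log2 fold change of 4.12, SE 0.12, and 14 of the 18 fell in blue light in the wild type. The groups do not say whether these differences belong to the genotype, to growth stage or to handling at harvest.

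Of the tests in the next 3 paragraphs, that on genes outside the range of the wild types was written before its result was seen, and all others after. CRY2, c-NAD-MDH1 and AT1G04420, next to each other in gene order, were under 5% of every other group in cry1 cry2. Against loss of light-activated cryptochrome signalling as the whole cause, the malate dehydrogenase stood at 0.0446% of the dark wild type, where cryptochromes are not activated by light. The 3 absent genes were all that the scan of cry1 cry2 found, and the next measured gene on each side stood at 145% and 115% of the wild type, which is in line with a deletion carried by the mutant line. Adjacent absent genes alone do not show a deletion, since the same scan found COR15A beside COR15B in the dark wild type and CYP81F4 beside AT4G37409 in the auxin receptor mutant. The series holds no DNA libraries, so a deletion stays a hypothesis. What the loss of the malate dehydrogenase adds to the other changes in cry1 cry2 stays open.

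In the dark auxin receptor mutant, photosynthesis genes were higher and root markers lower. Against scaling by a few abundant genes as the whole cause, the photosystem median was 1.93 before and 1.85 after quantile normalization, and the root hair median -1.56 before and -1.34 after. A changed share of one organ alone stays open: the SD of the members' log2 read ratios was 9.91 times their error over 28 photosystem genes (SD 0.567, error 0.0573) and 4.07 times over 20 root markers (SD 0.935, error 0.230), but genes also expressed in other organs would spread under a changed share too. Slower development stays open as well, and 14 of 15 seed reserve genes were higher. An effect of the receptors' loss on these genes is a hypothesis that the design cannot separate from organ share or growth stage.

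Genes at least 2-fold outside both wild-type groups in cry1 cry2 numbered 165, 142 above and 23 below, and 3 of the latter were CRY2 and its neighbours. Among those above were 9 of the 18 abscisic acid response genes, such as LEA7 and HAI1, beside RAB18 and the antenna gene LHCB1.5, and CHS was among those below. Over all tested genes, 142 of 20044 lay above. The abscisic acid group was chosen after its values were seen, so its 9 members are no independent test. Against scaling by a few abundant genes, 144 of the 165, or 87.3%, stayed 2-fold outside after quantile normalization. Since the series holds no dark cry1 cry2 group, an effect of genotype without light stays open and untested, as does any effect of the neighbours of CRY2.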
